A study of Drosophila melanogaster with 4 samples.

How the data were processed

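Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on nuclei of 3rd instar larvae of wild-type Oregon-R Drosophila melanogaster, with an affinity-purified rabbit polyclonal antibody against JMJD2A/KDM4A. The series held 4 samples: 2 ChIP libraries and 2 libraries of input DNA, numbered as replicates 1 and 2 of each kind in their titles. Tissue was homogenized, fixed with formaldehyde, lysed with SDS and sonicated, and precipitated on protein A Sepharose beads, per the labels' protocols. The free-text descriptions conflicted with the titles for some samples: the description of ChIP replicate 2 named input DNA, and that of input replicate 1 named antibody-precipitated DNA. Titles and source names gave the same assignment for all 4 samples and were used for the grouping. Nothing in the labels says whether the numbered replicates came from separate cultures of larvae, so their spread may be technical.

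One list of enriched regions was used for each ChIP replicate, together with 1 list for the series as a whole, called the combined list here. No region list of the input libraries was at hand. Reads were aligned with Bowtie 0.12.7, per the submitters' processing notes. Positions are 1-based on FlyBase release 5 of the genome, per the file headers. Every row used is typed as a region of significant enrichment, per the deposited lists. The peak caller, its threshold, the use of the input libraries and the way the combined list was made are not given in the sources used here. Each region carries the authors' own enrichment score, whose scale is not named in the deposited lists. The authors' scores were read as log2 values because differences among the 14 highest distinct scores equalled log2 of ratios of small whole numbers (denominators up to 30, tolerance 1e-09). This held for 34 of 91 pairs in replicate 1, 3 of 91 in replicate 2 and 38 of 91 in the combined list, against 0 to 2 of 91 for a natural or decimal log. In replicate 2 a natural log gave 0 of 91 and a decimal log 1 of 91. The log2 reading of replicate 2 scores therefore rests on few pairs. Scores were used to describe, rank and filter regions within a list, and levels were not compared between lists. Read totals are not given in the lists, so depth is unknown, and intervals and tests concern positions in these libraries rather than animals.

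The combined list had 1 row typed as depleted, at 3R 20999270 to 21000960, which was left out. In replicate 1 and in the combined list, 1 region each ran past the stated end of 3L and was counted up to that end. Covered share was the number of bases inside regions divided by the chromosome length in the file headers. The plan had named the last region end as the length in this case, and header lengths took its place once the headers had been read. Header lengths were not corrected for gaps or repeats where reads cannot be placed. Chromosomes were pooled into autosomal arms (2L, 2R, 3L and 3R), the X, chromosome 4, 6 heterochromatin scaffolds (2LHet, 2RHet, 3LHet, 3RHet, XHet and YHet) and the unplaced scaffold U. Uextra, 29.0 Mb of unplaced sequence, held 0 regions in all 3 lists and was left out of the assembly length of 139.7 Mb. The gene table at hand is of release 6, so its positions were not used, and the planned tests of transcription start sites, gene parts and gene lists were not run.

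A region was called found in another list when they shared at least 1 bp. Chance overlap was taken from 10000 random circular shifts of replicate 1 within each chromosome, with a one-sided empirical p whose smallest value is 1.00e-04. Shares of regions carry exact Clopper-Pearson 95% intervals, which cover counting error only. Covered shares and their ratios carry 95% intervals from 10000 bootstrap draws of 100 kb bins. Differences of medians were tested by two-sided permutation with 100000 resamples, whose smallest p is 1.00e-05 (10000 resamples and 1.00e-04 for the alternatives; the higher-scoring parts of the lists are among these), and X and arm scores also by a bootstrap of 100 kb blocks with 1000 draws. Permuting single regions treats neighbours as independent, so those p-values are too small where neighbours resemble each other. With 2 replicates no test across samples was made, and both values are given, with mean and SD. Named regions were the 10 highest-scoring and the 10 widest of the combined list, the rule set for the case in which gene positions of release 5 were not at hand. Groups, tests, the naming rule and most alternatives were fixed before the data were examined. The centromere-proximal windows, the comparison of X and arm scores and the shifts within chromosome 4 alone were added later. The plan also did not name the ratio for scaffold U or the splits of recovery and of combined regions by chromosome. Nor did it name replicate 2 as a share of replicate 1, the regions over 10 kb or the correlation across 100 kb bins.

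The overlap code was tested on simulated lists of the sizes of replicates 1 and 2. With 3468 planted copies, 60% of the second list, it found 60%. This checks the counting only, since the other regions were chosen to touch none of the first list. Among 20 simulated pairs of independent lists, with 200 shifts each, 1 had a p under 0.05. Regions of those pairs were placed at random, so the check does not cover lists whose regions cluster along a chromosome. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, with random seed 1, and plots used matplotlib 3.10.9. The alternatives tried were a stricter overlap, the higher-scoring part of each list, lists of equal length, random placement of regions (1000 draws), joined regions, other chromosome sets, other lengths, each replicate alone and the combined list.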

Results

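KDM4A is a JmjC-domain histone lysine demethylase of Drosophila and a known partner of heterochromatin protein HP1a. Its distribution in whole wild-type 3rd instar larvae was mapped by ChIP-seq in 2 replicates. Replicate 1 had 11489 enriched regions that covered 32.3 Mb, or 23.1% of the release 5 assembly without Uextra. Replicate 2 had 5780 regions that covered 15.8 Mb, or 11.3%. The combined list of the series had 11016 regions that covered 30.1 Mb, or 21.6%. Median region widths were 2164 bp, 2269 bp and 2085 bp in these lists, and the widest regions spanned 62290 bp, 20332 bp and 59615 bp. Read depth is unknown from the lists, so differences in the number of regions between the replicates carry no correction for it.

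At an overlap of at least 1 bp, nearly all KDM4A regions of replicate 2 recurred in the longer list of replicate 1. Most replicate 1 regions had no counterpart in replicate 2. Replicate 1 touched 5308 of the 5780 replicate 2 regions (91.8%, exact 95% interval 91.1 to 92.5). In the reverse direction 5262 of 11489 regions were found (45.8%, 44.9 to 46.7). Random circular shifts gave means of 40.3% and 20.8%, with highest values of 53.4% and 28.2%, so both overlaps exceeded chance (one-sided permutation of positions by shifting, p = 1.00e-04 each, the smallest the shifts can give). At 50% reciprocal overlap the shares fell to 67.8% and 34.1%. With replicate 1 reduced to its 5780 best-scoring regions they were 58.7% and 53.4%, against 23.7% and 21.3% under the shifts. Replicate 2 regions were thus found less often in the shorter list. The replicate 2 list stayed the same, so the rise for replicate 1 came from keeping only its best-scoring regions. The replicates shared 13.2 Mb of a joint 34.9 Mb, a Jaccard index of 37.9% against a mean of 8.73% under the shifts (same permutation, p = 1.00e-04). The shared bases made up 83.8% of replicate 2 and 40.9% of replicate 1. Across 1194 bins of 100 kb on the autosomal arms and the X, covered bases in the replicates correlated with r = 0.77 and rho = 0.80. Neighbouring bins are not independent, and no p is given.

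Recovery differed by chromosome. Of replicate 1 regions, 50.3% on the autosomal arms (49.2 to 51.4) and 51.6% on the X (49.3 to 53.9) were found in replicate 2. The share was 28.1% on chromosome 4 (36 of 128 regions, 20.5 to 36.8), 10.5% on scaffold U (46 of 440, 7.76 to 13.7) and 8.14% on the heterochromatin scaffolds (65 of 799, 6.33 to 10.3). In the other direction, replicate 1 touched all 83 replicate 2 regions of chromosome 4, 92.1% of those on the arms, 91.9% on the X, 87.7% on the heterochromatin scaffolds (64 of 73) and 70.6% on U (48 of 68). These shares carry no correction for chance, which varies with the density of regions. Replicate 2 had 46.5 regions per Mb on the arms, 7.86 on the heterochromatin scaffolds and 6.77 on U. Low recovery on the scaffolds thus largely restates how few replicate 2 regions lie there. On chromosome 4, shifts within the chromosome touched a mean of 93.0% of replicate 2 regions.

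The question behind the comparison of chromosomes was whether a partner of HP1a is concentrated on chromosome 4 and in pericentromeric sequence. Chromosome 4, a small and largely heterochromatic chromosome, had the highest covered share of the 5 parts of the assembly in both replicates. KDM4A regions covered 81.5% of it in replicate 1 (bootstrap 95% interval 73.3 to 88.0) and 21.4% in replicate 2 (17.6 to 24.8). The autosomal arms were covered to 23.7% (22.7 to 24.6) and 12.8% (12.1 to 13.5). The ratio of chromosome 4 to the arms was thus 3.44 (3.08 to 3.76) and 1.67 (1.37 to 1.95), with a mean of 2.56 ± 1.25 (SD, n = 2) and 3.13 in the combined list. Both intervals lay above equality, but the size of the excess differed between replicates by more than either interval. Counted as regions per Mb instead of covered bases, the ratio was 1.10 in replicate 1 and 1.32 in replicate 2, with a mean of 1.21, so the larger excess was then in replicate 2.

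With the full lists, the heterochromatin scaffolds matched the arms in replicate 1 and fell far below them in replicate 2. Their covered share was 23.8% (21.2 to 26.4) and 1.92% (1.34 to 2.54), and their ratio to the arms was 1.00 (0.890 to 1.12) and 0.150 (0.104 to 0.200), with a mean of 0.577 ± 0.604 (SD, n = 2). In replicate 1, XHet was covered to 28.0%, 3LHet to 27.6%, 3RHet to 23.6%, 2RHet to 23.0%, 2LHet to 19.6% and YHet, from the Y chromosome, to 6.13%. In replicate 2 the highest share among them was 3.85%, on XHet, and the lowest 0.402%, on YHet. Scaffold U lay below the arms in both replicates, with ratios of 0.431 (0.362 to 0.505) and 0.146 (0.0912 to 0.211). Lengths were not corrected for sequence where reads cannot be placed. Low ratios on U and the heterochromatin scaffolds therefore need not mean less KDM4A there. In the higher-scoring part of each list and with replicate 1 reduced to the length of replicate 2, the mean ratio rose from 0.289 to 0.476 and 0.436 for U, and from 0.577 to 0.899 and 0.884 for the heterochromatin scaffolds. When reduced, replicate 1 covered 21.7% of the heterochromatin scaffolds against 13.4% of the arms, so its match with the arms did not hold there. With the full lists the X did not differ detectably from the arms, with ratios of 0.959 (0.868 to 1.05) and 0.953 (0.847 to 1.07). Its mean ratio lay on the other side of equality in the higher-scoring part of each list (1.14) and with replicate 1 reduced (1.07). Single arms ranged from 21.7% on 3R to 25.5% on 2R in replicate 1, and from 11.7% on 2L to 15.0% on 2R in replicate 2.

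**Figure D1:**
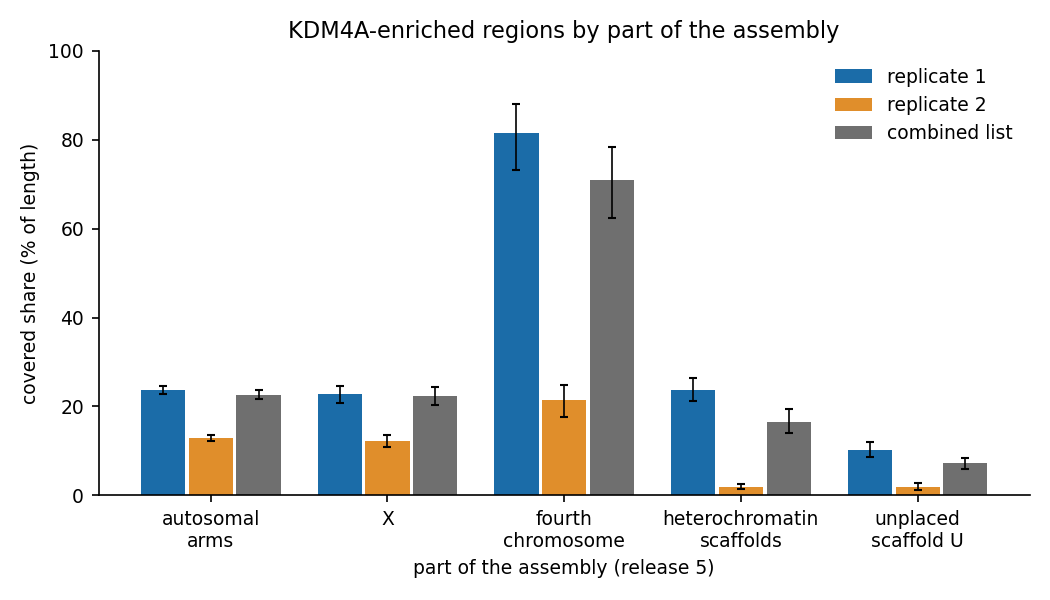
Share of each part of the release 5 assembly covered by KDM4A-enriched regions (y axis, % of length) for the 5 parts (x axis); bars are the lists of replicate 1, replicate 2 and the series, and error bars are bootstrap 95% intervals over 100 kb bins. Chromosome 4 stands highest in each list, at 81.5%, 21.4% and 71.0%, and the heterochromatin scaffolds stand at 23.8%, 1.92% and 16.6%.

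Relative to replicate 1, replicate 2 covered less of chromosome 4 and of the scaffolds than of the arms. Bases covered in replicate 2 came to 54.1% of those in replicate 1 on the arms (52.3 to 56.0) and 53.8% on the X (50.6 to 57.0). The same figure was 26.3% on chromosome 4 (22.5 to 29.7), 18.4% on U (12.1 to 24.7) and 8.08% on the heterochromatin scaffolds (5.97 to 10.2). When replicate 1 was reduced to its 5780 best-scoring regions, the length of the replicate 2 list, with each region at its full width, it covered 77.2% of chromosome 4 and 21.7% of the heterochromatin scaffolds, against 13.4% of the arms, 15.9% of the X and 9.73% of U.

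On chromosome 4, replicate 1 formed long domains and replicate 2 short separate regions. Of the bases covered there, 68.5% lay in regions over 10 kb in replicate 1, 3.69% in replicate 2 and 64.0% in the combined list. Replicate 1 had 32 such regions on chromosome 4 among 147 in the genome, and replicate 2 had 1 among 29. The longest gap between regions was 15.8 kb in replicate 1 and 78.7 kb in replicate 2 (719065 to 797724). Replicate 1 regions contained 99.0% of the bases of replicate 2 regions, against a mean of 81.4% and a highest value of 99.2% in 10000 circular shifts within chromosome 4 (one-sided permutation of positions by shifting, p = 5.00e-04). All 83 replicate 2 regions were touched, against a mean of 93.0% under the shifts (same permutation, p = 0.0038).

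**Figure D2:**
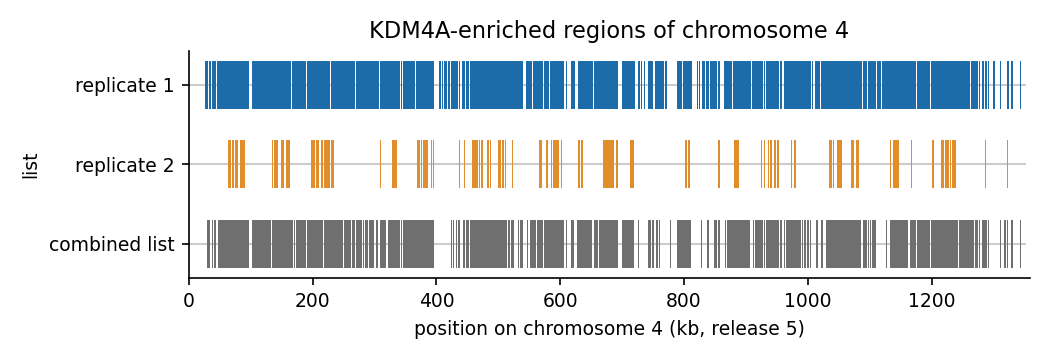
Positions of KDM4A-enriched regions along chromosome 4 (x axis, kb on release 5) in the lists of replicate 1, replicate 2 and the series (y axis); each block is a region drawn to scale on a grey line for the chromosome. Replicate 1 fills 81.5% of the chromosome and replicate 2 fills 21.4%, with its longest gap from 719065 to 797724.

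Near the centromeres the replicates moved in opposite directions. In the 2 Mb nearest the centromere of 2L, 2R, 3L, 3R and X pooled, replicate 1 covered 32.9% against 22.6% in the rest of the arms, a ratio of 1.45 (bootstrap 95% interval 1.30 to 1.62). Replicate 2 covered 8.22% against 13.1%, a ratio of 0.627 (0.497 to 0.773). In replicate 1 the proximal share was 44.9% on 2R (23.5% in the rest of the arm), 36.6% on 2L (22.1%), 34.4% on 3L (23.7%) and 31.7% on 3R (21.0%). On the X it was 16.8% (23.3%), where the intervals overlapped (11.1 to 23.0 and 21.3 to 25.4). In replicate 2 it was 8.87% on 2R (15.6%), 7.47% on 2L (12.1%), 3.60% on 3L (12.7%) and 5.83% on the X (12.8%), and on 3R it was 15.3% (12.7%), where the intervals overlapped. The combined list had a pooled ratio of 1.21 (1.04 to 1.38).

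**Figure D3:**
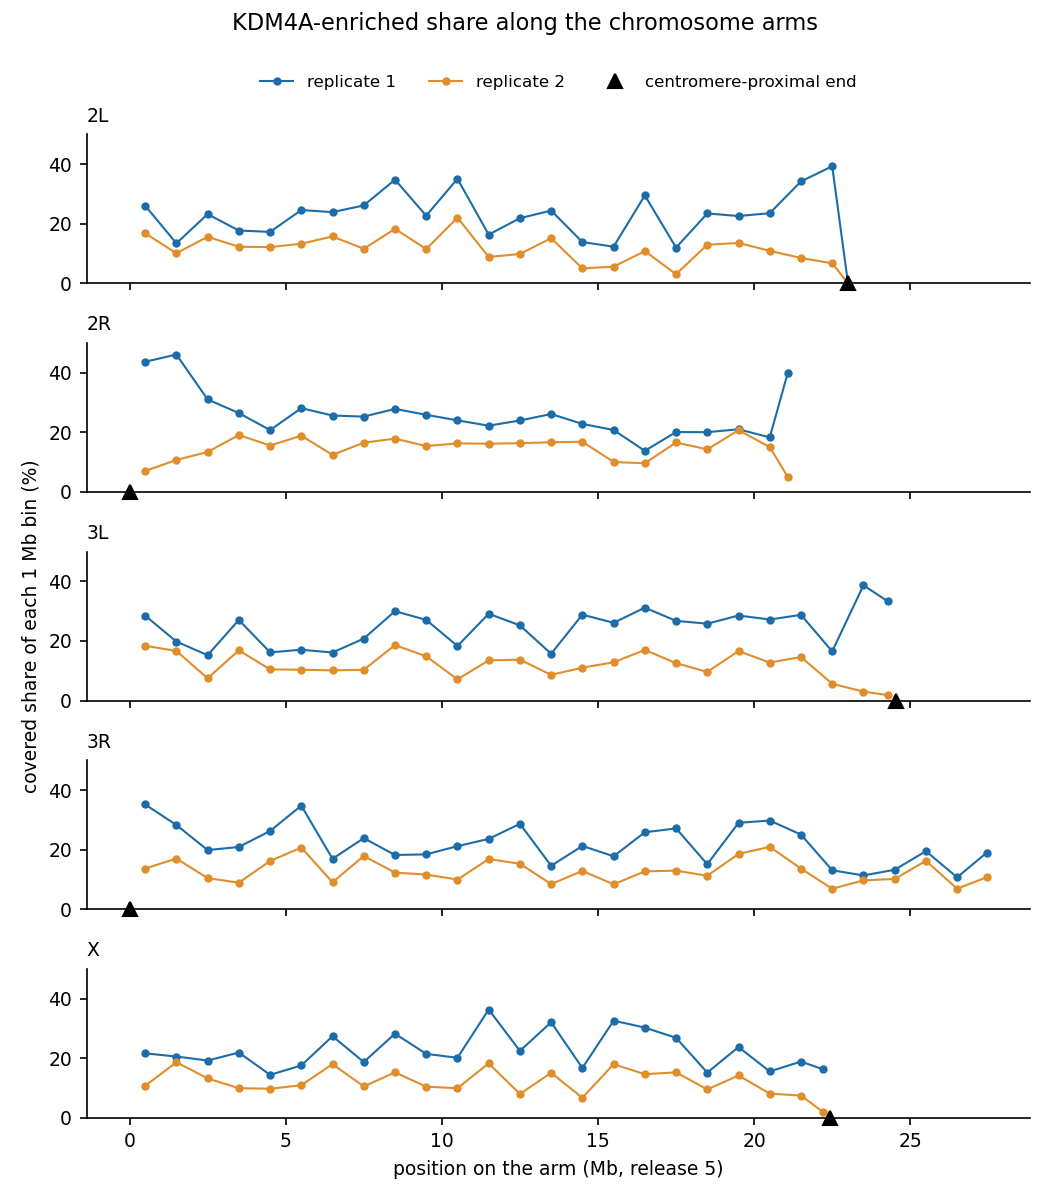
Share of each 1 Mb bin covered by KDM4A-enriched regions (y axis, %) along 2L, 2R, 3L, 3R and X (x axis, Mb on release 5) in replicate 1 and replicate 2; triangles mark the centromere-proximal ends, and the last bin of each arm is shorter than the others. The lines diverge toward the centromeres of 2L, 2R and 3L, where replicate 1 covers 36.6%, 44.9% and 34.4% of the proximal 2 Mb and replicate 2 covers 7.47%, 8.87% and 3.60%.

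Regions on the X scored higher than those on the autosomal arms in both replicates. The median log2 score was 0.89 on the X and 0.76 on the arms in replicate 1, a difference of 0.12 (block-bootstrap 95% interval 0.09 to 0.15). In replicate 2, where the log2 reading rests on few pairs, the median was 0.78 and 0.66, a difference of 0.12 (0.09 to 0.15). The combined list gave 0.53 and 0.46, a difference of 0.07 (0.05 to 0.08). Two-sided permutation tests gave p = 1.00e-05 in each list, the smallest the resamples can give. In the higher-scoring part of each replicate list, the mean of the 2 replicate differences was 0.024. The mean was not tested, and the larger of the 2 replicate p-values was 0.112 (two-sided permutation).

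In the combined list, regions found in both replicates numbered 4917 of 11016 (44.6%, exact 95% interval 43.7 to 45.6). A further 4276 regions (38.8%, 37.9 to 39.7) were found in replicate 1 alone, 410 (3.72%, 3.38 to 4.09) in replicate 2 alone and 1413 (12.8%, 12.2 to 13.5) in neither. On chromosome 4, 121 of 158 combined regions were found in replicate 1 alone, with a median width of 2133 bp, and 31 in both, with a median width of 16447 bp. On the heterochromatin scaffolds, 488 of 711 were in replicate 1 alone (median width 1625 bp) and 62 in both (5183 bp), and on U 167 of 400 regions were in neither. On the arms, 3879 of 7886 were in both (49.2%) and 829 in neither (10.5%). Conversely, 97.6% of replicate 2 regions and 79.6% of replicate 1 regions were found in the combined list. The shares depended on the score: in the higher-scoring part of the combined list, 70.3% were in both, 21.0% in replicate 1 alone and 0.309% in replicate 2 alone.

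Combined regions found in both replicates were stronger and wider than the rest. Their median log2 score was 0.75 against 0.42, a difference of 0.33, and their median width 3047 bp against 1537 bp, a difference of 1510 bp. Two-sided permutation tests gave p = 1.00e-05 for each, the smallest the resamples can give. Neither difference is independent of the overlap: the combined list belongs to the same series as the replicate lists that define it, and wider regions have more room to touch another region.

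Of the 10 widest regions of the combined list, 8 lay on chromosome 4, and each of the 10 was touched by regions of both replicates. The widest, 4 454062 to 513676 (59.6 kb, score 1.08), was covered to 99.0% in replicate 1 and 45.9% in replicate 2. The next, 4 1028882 to 1086756 (57.9 kb, score 1.19), was covered to 99.1% and 50.0%. The other 6 on chromosome 4 started at 59978, 217846, 367122, 573226, 664574 and 1132620 and were 28.6 to 37.1 kb wide. The 2 outside it were 2L 10237412 to 10282928 (45.5 kb, score 1.15), covered to 92.7% in replicate 1 and 77.5% in replicate 2, and 3L 222408 to 252292 (29.9 kb, score 0.91), covered to 85.9% and 71.2%. Over these 10 regions the covered share ran from 85.9% to 100% in replicate 1 and from 36.9% to 77.5% in replicate 2.

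The 10 best-scoring combined regions were short, 1001 to 1897 bp, with log2 scores of 3.50 to 3.96. The pair with the highest score, 3L 21206 to 23102 and 3L 24134036 to 24135334, had no region in either replicate. Of the 10, 2 lay on U, 3 on the heterochromatin scaffolds and 5 on the arms. Only 3RHet 2328578 to 2329578 was touched by replicate 1, over 29.4% of its length, and 0 were touched by replicate 2. In the whole combined list, 14 regions were tied at the lowest of these scores, so the last places were filled by chromosome order.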

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

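The comparisons without chromosome 4 and the scaffolds for the combined list, the proximal windows, the X scores, header lengths in place of last region ends and replicate 1 reduced for covered shares were chosen after seeing the data. Of 66 alternative values, 48 stayed within the spread or on the same side of the test. For ratios to the arms the spread was 1 SD of the 2 replicate values, which is wide where the replicates disagree. It was 1.25 for chromosome 4 and 0.604 for the heterochromatin scaffolds. The count therefore does not measure how stable those ratios are. Across settings, replicate 2 regions found in replicate 1 ranged from 58.7% to 92.0% and the reverse from 34.1% to 53.4%, above chance in each. Of 21 tested alternatives, 20 kept their side of p = 0.05; the exception was the X score difference in the higher-scoring part of each list, 0.024 (permutation p = 0.112, 10000 resamples), where a common lower score limit trims both groups. Asking for 50% of a combined region's length gave 39.4% in both replicates, 42.4% in replicate 1 alone and 14.4% in neither. The higher-scoring part gave 70.3%, 21.0% and 8.44%, with 0.309% in replicate 2 alone, and the arms and X gave 49.0%, 35.8% and 11.1%. The X to arm ratio became 0.981 by regions per Mb, 1.14 in the higher-scoring part, 0.985 in the combined list and 1.07 with replicate 1 reduced, so it crossed equality, which the intervals of both replicates span. In the higher-scoring part and with replicate 1 reduced, the mean ratio was 0.899 and 0.884 for the heterochromatin scaffolds (0.577 with full lists), 0.476 and 0.436 for U (0.289), and 3.67 and 3.71 for chromosome 4 (2.56). In the reduced setting replicate 2 was unchanged, so the mean rose through replicate 1 alone. Replicate 1 then covered 77.2% of chromosome 4 and 21.7% of the heterochromatin scaffolds against 13.4% of the arms, so the replicates diverged further. Ranking by score favours the parts where replicate 1 scores are higher. The chromosome 4 ratio fell to 1.21 by regions per Mb, since its regions are wide. The proximal ratio of replicate 1 rose to 1.90 in its higher-scoring part and 1.89 when reduced. For these X, support and proximal shifts the cause was not tested. Single replicates gave ratios to the arms of 0.953 to 0.959 for the X, 1.67 to 3.44 for chromosome 4, 0.150 to 1.00 for the heterochromatin scaffolds and 0.146 to 0.431 for U; with n = 2 these lie within 1 SD by construction. No paired analysis was possible because no region list of the input libraries, which share the replicate numbers, was at hand to set against the ChIP lists. The settings planned for transcription start sites, gene parts and gene lists were not run, as gene positions of release 5 were not at hand. Read depth is unknown, so its part in the replicate difference has no bound.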

Other observations

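The tests below were chosen after the results they bear on had been seen, except the width-matched comparison of X scores. Recovery of replicate 1 regions in replicate 2 was highest in the top score decile on the arms, on chromosome 4 and on the heterochromatin scaffolds, at different levels; the difference in trend was not tested. In the highest decile of replicate 1 scores, 87.4% of arm regions were found in replicate 2 (450 of 515), against 79.4% on chromosome 4 (27 of 34) and 17.9% on the heterochromatin scaffolds (34 of 190). In the ninth decile the shares were 83.4% on the arms (574 of 688), 11.8% on chromosome 4 (2 of 17) and 4.35% on the heterochromatin scaffolds (7 of 161). Off the arms the lower deciles showed no steady rise, on small counts. On the heterochromatin scaffolds the share was 14.8% in the fourth decile (4 of 27) and 2.68% in the eighth (4 of 149). On chromosome 4 it was 16.7% in the fifth (1 of 6), 20% in the eighth (3 of 15) and 11.8% in the ninth (2 of 17). Arm recovery was lowest in the third decile, at 34.9%, and stood at 45.1% in the first.

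Chromosome 4 and the heterochromatin scaffolds were covered far more in replicate 1 than in replicate 2, beyond the difference on the arms. Lower scores in replicate 1 are argued against. Its median scores were 1.10 on chromosome 4 and 1.20 on the heterochromatin scaffolds, against 0.76 on the arms. Median widths were 4037.5, 2115 and 2181 bp. Of chromosome 4 regions, 28.1% were found in replicate 2 (exact 95% interval 20.5 to 36.8), against 64.5% for arm regions of the same score decile and width quintile. For heterochromatin regions the shares were 8.14% (6.33 to 10.3) and 44.9%. Matching on score and width left the deficit in place, but the deficit largely restates the scarcity of replicate 2 regions there. An equal score need not mean equal read support, so weaker read support remains open. A cut by score alone did not remove the excess on the heterochromatin scaffolds. There the best-scoring 5780 regions of replicate 1 covered 21.7%, against 1.34 to 2.54% in replicate 2. This follows from the higher scores there, since the cut kept 701 of 799 heterochromatin regions and 3527 of 8298 arm regions. It therefore cannot decide how loose the calling threshold was, which is not known. On chromosome 4 the same reduction left 77.2%, which decides nothing because the wide regions there keep their full width. That replicate 2 is mislabelled, as its description could be read, cannot be told apart from a true ChIP library without an input list. Of its regions, 91.8% were touched by replicate 1 (40.3% by chance). Scores of 3851 regions matched at 50% reciprocal overlap on the arms and X correlated between the replicates (r = 0.74, rho = 0.71, across regions that are not independent). A threshold on significance rather than score, the treatment of repeated reads, the input correction and a difference between the larvae remain open, and no biological explanation was tested since the design holds a single condition.

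Higher scores on the X may reflect width or a stricter bar for calling X regions, among other causes. Width is argued against, since X regions were not wider than arm regions by median. The medians were 2167.5 against 2181 bp in replicate 1 and 2260 against 2281 bp in replicate 2. Matching on width could therefore remove little of the difference. Within width deciles the X exceeded the arms by 0.11 in replicate 1 (block-bootstrap 95% interval 0.10 to 0.14) and 0.11 in replicate 2 (0.08 to 0.13). A stricter bar alone would remove weak regions and add no strong ones, yet regions at or above the 90th percentile of arm scores were 1.44 times as dense on the X in replicate 1 (12.4 against 8.59 per Mb, interval 1.22 to 1.69) and 1.59 times in replicate 2 (7.40 against 4.66 per Mb, 1.30 to 1.91). This second test replaced a comparison of the 90th percentiles themselves (X higher by 0.15 and 0.14), which a stricter bar would also raise. The greater density of strong regions restates the higher scores and gives no cause for them. X scores were also higher at the 10th percentile, by 0.08 in each replicate, and an even shift of all X scores was not tested. Noise from a lower read depth on the X was not tested, and the design gives no group for a biological explanation.

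The best-scoring regions of the combined list were narrow and rarely seen in the replicates. Among the top 100, the median width was 1032 bp against 2085 bp in the whole list, 69 were in neither replicate, 51 lay on U and 17 on the heterochromatin scaffolds. Scores tied exactly with another region made up 77% of the top 100, above the highest of 1000 random draws (range 10 to 43%, mean 26.2%), which is consistent with ratios of few reads behind those scores. Reads shared among repeats on U remain open, and no biological explanation was tested.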
